A study of Rattus norvegicus with 9 samples.

How the data were processed

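Poly(A) RNA of primary rat nucleus pulposus cells was sequenced in 9 libraries, made with the VAHTS Universal V6 kit from TRIzol-extracted RNA, per the labels. Cells grew in high-glucose medium with 10% serum. The series has 3 groups of 3 libraries, named NC, SEN and BNPMT in the sample titles. Per the labels, senescence was induced by doxorubicin at 200 nM over 24 h and 6 more days in new medium, and BNPMT was an intervention in it. The protocol text with doxorubicin is the same on all samples, NC included, and NC was taken as the untreated control from its title and from the series' design text.

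The submitters' processing notes name fastp, HISAT2, HTSeq and the rat build mRatBN7.2, with no versions, roles or order. The annotation and the strandedness of the counting are not given in the sources used here, so reads of overlapping genes, and of antisense genes if strand was ignored, cannot be told apart. The authors deposited a table of whole-number counts per gene, with 22324 genes, and an FPKM table. Each deposited FPKM value equals the count over the gene's length times the library's total count (largest relative difference 8.52e-16). The deposited FPKM files of single samples hold the same values as that table (largest difference 1.02e-07). All results come from the counts, except 2 alternatives on FPKM and the transcript lengths, which rest on FPKM as described. No pair of libraries was a duplicate, with a chi-square per degree of freedom of 3.51 to 33.5 within groups.

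Total counts per library were 34514440, 40485232 and 41873790 in NC, 38391586, 31206834 and 35364168 in SEN, and 41812986, 35094282 and 41971877 in BNPMT. A count of 3, used as the floor for a gene without counts, is worth 0.0715 to 0.0961 CPM (counts scaled to the total of the library) in a library. CPM values in the text are per total count, with the SD over libraries, as are ratios of counts and folds against the floor, whereas log2 changes are scaled by TMM factors.

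Genes were kept with edgeR's filterByExpr, which left 14956 genes. Changes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on all 9 libraries in a layout of 3 groups, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Adjusted p-values of genes are from that test. A gene counted as reversed when it was called in SEN against NC and called with the opposite sign in BNPMT against SEN. The share undone was minus the ratio of the BNPMT against SEN change to the SEN against NC change on the log2 scale. Ratios for genes with 1 to 3 counts in a group carry a 95% counting interval.

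Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists, and adjusted p-values of lists are from that test. An estimated correlation and fry were alternatives. The ranges and calls of lists over 17 alternatives leave out fry. The 35 lists cover p53 targets, S phase, G2 and mitosis, DNA repair, senescence markers and secretory genes, NF-kappaB and TGF-beta targets, interferon and DNA sensing, mitochondria, apoptosis, mitophagy, disc matrix and proteases, other cell types, and stress and metabolism. A list needed 5 tested members, which erythroid markers lacked. KEGG pathways of 15 to 300 members were tested in the same way, a step added after the data were seen.

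The named genes were, in each comparison, 21 fixed genes, the 5 largest rises and the 5 largest falls, up to 4 members of each called list with the smallest adjusted p in its direction, and the 8 most strongly reversed genes. Largest changes were taken among genes with a name that is not a placeholder, an adjusted p below 0.05, a mean of at least 5 CPM over the compared groups and no overlap of the groups. Of the genes this rule named, 3 are not reported here. The groups, tests, lists, the rule for named genes and all alternatives but 3 were chosen before the data were examined.

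Alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, a 2-fold minimum, a fit of the 2 compared groups, a replicate block, a robust dispersion prior, thinning to the smallest library, leaving out mitochondrially encoded genes, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), whose added constant understates the changes of low genes, and leaving out each library. The 3 chosen after seeing the data were total counts alone, taking each library's trend with transcript length out by a loess curve, and leaving out SEN 1 and BNPMT 1 together.

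The count model was tested on counts simulated independently per gene from the real means, library sizes and estimated dispersions. At each fold size 50 genes were changed. For SEN against NC (13886 genes) 88% of 1.5-fold and 98% of 2-fold changes were recovered, and 18 unchanged genes were called. For BNPMT against SEN (14568 genes) the shares were 68% and 96%, with 10 unchanged genes called, and for BNPMT against NC (13903 genes) 84% and 100%, with 6. All 4 and 8-fold changes were recovered. In each comparison camera called a list shifted by 0.5 (log2) and 0 of 26, 27 and 26 unchanged lists. Independent genes do not test the preset correlation.

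No genome was used. Neighbouring genes were taken from a RefSeq gene table of the assembly GRCr8, matched by gene ID for 21032 of 22324 genes (94.2%), and no coordinates are reported. GC content was not analysed here.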

Results

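Nucleus pulposus cells are those of the gel-like core of the intervertebral disc. The 9 libraries formed 3 groups of 3. NC was taken as the untreated control, although the protocol text with doxorubicin stands on every sample. SEN cells had been made senescent with doxorubicin, a DNA-damaging drug. BNPMT cells were labelled as doxorubicin-induced senescence with an intervention called BNPMT. The labels do not expand that name, and they give neither its dose nor its timing. The study's title speaks of the stability of the mitochondrial outer membrane and of sequestering extracellular DNA. The deposited tables gave 22324 genes, 17949 of them protein-coding. Total counts per library were 34514440 to 41873790 in NC, 31206834 to 38391586 in SEN and 35094282 to 41971877 in BNPMT. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Counting intervals and floors cover counting error only.

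The SEN libraries stood far from both other groups. Spearman correlations of counts across genes were 0.973 to 0.979 between NC and BNPMT libraries, 0.932 to 0.934 between NC and SEN, and 0.923 to 0.931 between SEN and BNPMT. Within groups they were 0.979 to 0.983. The largest principal component of log2 CPM (counts scaled to the total of the library) held 85.1% of the variance and parted SEN from the rest, and the next held 8.2% and parted NC from BNPMT. SEN 1 and BNPMT 1 stood apart within their groups. On that component SEN 1 scored 9.72 against -2.59 and -1.46, and BNPMT 1 scored 19.12 against 40.36 and 36.21. Transcript length went with those distances: the Spearman correlation across genes of a library's deviation from its group with length was -0.42 for SEN 1 and 0.51 for BNPMT 1. It was 0.26 for SEN 2, 0.23 for SEN 3, -0.43 for BNPMT 2 and -0.32 for BNPMT 3, and lay between -0.20 and 0.15 in the NC libraries.

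**Figure D1:**
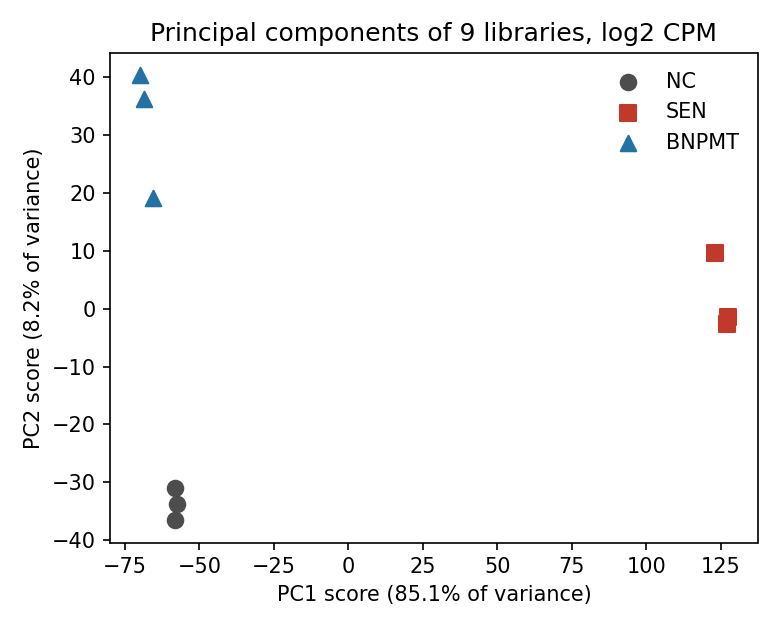
Principal component scores of the 9 libraries, computed on log2 CPM scaled by TMM factors. Each axis gives the component's share of the variance, and each point is 1 library. The 3 SEN libraries lie apart along the component that holds 85.1% of the variance, and NC and BNPMT libraries part along the component that holds 8.2%.

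Log2 changes are relative to scaling by trimmed means of M-values (TMM). CPM values, count ratios and folds against the floor are per total count. The TMM factors averaged 1.097 in NC, 0.802 in SEN and 1.136 in BNPMT. With total counts alone as the scale, the median log2 change of all tested genes was -0.46 for SEN against NC, 0.52 for BNPMT against SEN and 0.06 for BNPMT against NC, compared with -0.01, 0.02 and 0.00 under TMM. A log2 change in a comparison with SEN that is opposite in sign to that shift and smaller than it can turn with total counts.

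The comparison of SEN with NC asks what doxorubicin-induced senescence changed. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose from 133 ± 1.91 CPM in NC to 1061 ± 45.5 CPM in SEN (SD, n = 3), a log2 change of 3.45 ± 0.06 (SE, adjusted p = 1.21e-14). Lmnb1, the nuclear lamina gene whose loss marks senescent cells, fell from 61.9 ± 1.34 to 12.8 ± 1.17 CPM, and Plk1, a mitotic kinase, fell from 45.4 ± 0.820 to 4.08 ± 0.580 CPM. Secreted factors rose, among them the chemokine gene Cxcl1, from 2.65 ± 0.370 to 107 ± 3.53 CPM, and the collagenase gene Mmp13, from 9.80 ± 0.293 to 40.8 ± 4.34 CPM. Immediate early and heat shock genes rose steeply, with Egr1 at 149.9 ± 5.25 CPM in NC and 5900.1 ± 181 CPM in SEN. Of 20 smooth muscle markers 16 fell and 3 rose. Of 13 mitochondrially encoded genes 10 fell and 1 rose, a list call lost with an estimated correlation.

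Among the fixed markers, the lysosomal galactosidase gene Glb1 rose by a log2 change of 0.87 ± 0.06, Il6 by 3.59 ± 0.41 and the matrix protease gene Mmp3 by 3.35 ± 0.07. Il6 remained a low-level transcript, at 2.92 ± 0.464 CPM in SEN. Cdkn2a, which encodes p16, had a log2 change of 0.37 ± 0.11 (adjusted p = 0.00634) under TMM and of -0.08 with total counts, so its direction depended on the scale. The call ended there (adjusted p = 0.461), with both FPKM alternatives and with the length trend taken out, and over 23 alternatives its adjusted p lay between 0.00147 and 0.461. Its level was 10.9 ± 0.187 CPM in NC and 10.3 ± 0.846 CPM in SEN. The direction of Sox9, the cartilage transcription factor, also depended on the scale, at 0.43 ± 0.07 under TMM and -0.02 with total counts (adjusted p = 0.755, between 1.37e-09 and 0.755 over 23 alternatives). The proliferation marker Mki67 did not pass the test at 0.09 ± 0.07 (adjusted p = 0.22), and its direction depended on the setting. It was called lower with total counts (log2 change -0.36, adjusted p = 0.000265), with both FPKM alternatives (adjusted p = 0.00101 and adjusted p = 0.00092) and with the length trend taken out (adjusted p = 0.000346), and higher without SEN 1 and BNPMT 1 (log2 change 0.14, adjusted p = 0.00985). Over 23 alternatives its adjusted p ranged up to 0.725. The matrix protease gene Adamts5 fell by 1.59 on the log2 scale. Il1b had 0 counts in NC and in SEN. With total counts Glb1, Acan, Col2a1, Cgas, Vdac1 and Bax kept direction and call at log2 changes of 0.42, 0.21, 0.51, -0.89, -0.84 and 0.28, moves of over 1.5 times. So did Sting1 at 0.34, Vdac1 at -0.64 and Bax at 0.24 with the length trend taken out.

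The list of p53 targets, genes raised after DNA damage, rose. Of 34 tested members 22 rose, 4 fell and 8 did not pass the test, with a median log2 change of 0.80 (camera, adjusted p = 1.17e-10). With total counts 18 rose and 11 fell, and with the length trend taken out 21 and 9. Mdm2, which encodes a ubiquitin ligase, rose from 70.8 ± 2.85 to 824 ± 21.6 CPM, the kinase gene Plk2 from 30.4 ± 0.843 to 561 ± 11.3 CPM, and the anti-proliferative gene Btg2 from 56.6 ± 1.18 to 754 ± 6.50 CPM. Genes of G2 and mitosis moved the other way: 42 of 57 fell, 7 rose and 8 did not pass the test, with a median of -0.61 (adjusted p = 1.65e-06). Ccnb1, the mitotic cyclin, fell by 1.97 on the log2 scale, and the mitotic kinesin gene Kif20a fell by 1.47. S phase and DNA replication genes were not called as a list, with 14 higher, 23 lower and 13 not passing of 50 (adjusted p = 0.87). Their counts were 10 higher and 36 lower with total counts, and 12 and 31 with the length trend taken out. Of 43 genes of DNA repair and the damage response 31 fell and 7 rose, with a median of -0.52, and that list was not called either (adjusted p = 0.0713, between 0.046 and 0.211 over 17 alternatives). It was called without NC 1 (adjusted p = 0.0487) and with total counts (adjusted p = 0.046).

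Inflammatory and secretory genes rose together. Of 55 tested genes of the senescence-associated secretory phenotype 46 rose and 7 fell, with a median log2 change of 1.77 (adjusted p = 3.07e-16). Hbegf, a growth factor gene, rose from 103 ± 2.51 to 1566 ± 33.4 CPM, and Plaur, the urokinase receptor gene, from 15.8 ± 0.169 to 278 ± 9.51 CPM. Of 30 NF-kappaB targets 23 rose and 3 fell (24 and 3 adjusted over the list alone), with a median of 1.71 (adjusted p = 1.16e-09). Ptgs2, the inducible cyclooxygenase gene, rose from 41.1 ± 3.93 to 1758 ± 268 CPM, and Nfkbia, which encodes the inhibitor of NF-kappaB, rose by a log2 change of 3.53 ± 0.09. Of 23 genes widely used as raised in senescence 18 rose and 4 fell, with a median of 1.30 (adjusted p = 4.85e-08). That call was not kept with a correlation estimated from the data (adjusted p = 0.18 with an estimated correlation). The 13 genes widely used as lowered in senescence held 5 that rose and 5 that fell and were not called (adjusted p = 0.778). Matrix-degrading proteases were not called either, with 20 of 33 higher and 10 lower (21 and 10 adjusted over the list alone, adjusted p = 0.0632, between 0.0368 and 0.299 over 17 alternatives). They were called without SEN 1 (adjusted p = 0.0499) and without SEN 2 (adjusted p = 0.0368).

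Immediate early and heat shock genes respond within minutes to stress, and all 32 of them rose in SEN, 30 of them with total counts as well. Their median log2 change was 3.35 (adjusted p = 5.14e-83) and 2.90 with total counts. Hspa1a and Hspa1b, near-identical genes of the inducible heat shock protein, rose by 6.95 ± 0.08 and 7.47 ± 0.09. Reads can be split between those copies, so the share of each is uncertain. Atf3, a stress transcription factor gene, rose from 19.0 ± 0.917 to 735 ± 36.2 CPM. The list's mean log2 CPM was 5.68 ± 0.014 in NC, 8.87 ± 0.031 in SEN and 5.68 ± 0.022 in BNPMT (SD, n = 3).

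Further stress lists rose in SEN. Of 42 genes of NRF2 and antioxidant defence 32 rose and 5 fell (32 and 6 adjusted over the list alone), with a median of 0.77 (adjusted p = 1.54e-07, and adjusted p = 0.21 with an estimated correlation). Hmox1, which encodes the heme-degrading enzyme, rose from 110.3 ± 0.502 to 2855 ± 97.2 CPM, and the thioredoxin reductase gene Txnrd1 from 125 ± 3.50 to 865 ± 24.4 CPM. Genes of the unfolded protein and amino acid stress responses rose in 25 of 40 cases and fell in 11, with a median of 0.52 (adjusted p = 0.00763, and adjusted p = 0.44 with an estimated correlation). With total counts 16 rose, 18 fell and the list was not called (adjusted p = 0.11, between 0.000649 and 0.438 over 17 alternatives). Hspa5, the main chaperone gene of the endoplasmic reticulum, rose from 1375 ± 6.04 to 3746 ± 149 CPM. Lysosomal genes rose in 36 of 43 cases and fell in 5, with a median of 0.94 (adjusted p = 1.81e-07, and adjusted p = 0.12 with an estimated correlation). Ctsd, which encodes the protease cathepsin D, rose from 432 ± 6.53 to 1008 ± 28.5 CPM. Glycolysis and hypoxia genes rose in 28 of 34 cases and fell in 4, with a median of 0.82 (adjusted p = 3.38e-08, and adjusted p = 0.18 with an estimated correlation), among them Vegfa, from 65.2 ± 1.84 to 286 ± 10.4 CPM, and the glucose transporter gene Slc2a1, from 65.4 ± 1.57 to 237 ± 3.92 CPM.

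Matrix genes of the cartilage type rose in SEN. Of 37 members 31 rose and 2 fell, with a median log2 change of 1.44 (adjusted p = 3.38e-08, and adjusted p = 0.17 with an estimated correlation). Col2a1, the main collagen gene of the nucleus pulposus, rose from 4571 ± 119 to 6492 ± 84.3 CPM, Col11a2 from 33.6 ± 0.973 to 208 ± 5.91 CPM, and Acan, which encodes aggrecan, from 587 ± 10.4 to 681 ± 34.5 CPM, a log2 change of 0.67 ± 0.06. Annulus and fibroblast markers rose in 21 of 29 cases and fell in 7, with a median of 0.39 under TMM and -0.06 with total counts (adjusted p = 0.0114, and adjusted p = 0.18 with an estimated correlation). The call of that list ended with total counts (adjusted p = 0.0843) and with the length trend taken out (adjusted p = 0.074), and its adjusted p lay between 0.00797 and 0.183 over 17 alternatives. Eln, the elastin gene, rose from 235 ± 3.62 to 732 ± 17.1 CPM. Smooth muscle and myofibroblast markers fell in 16 of 20 cases and rose in 3, with a median of -1.13 (adjusted p = 9.18e-07). The smooth muscle myosin gene Myh11 fell from 110.3 ± 2.38 to 6.70 ± 0.545 CPM, and the actin gene Acta2 from 2387 ± 7.26 to 389 ± 21.2 CPM. Markers of nucleus pulposus and notochord cells were not called (10 of 24 higher, 11 lower, adjusted p = 0.859), with a median of -0.30 and a mean of 0.03.

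Transcripts of the mitochondrial genome fell in 10 of 13 cases and rose in 1. Their median was -0.80 (adjusted p = 0.00315, and adjusted p = 0.21 with an estimated correlation). ND4, a subunit gene of respiratory complex I, fell from 3118 ± 49.6 to 761 ± 61.3 CPM, and COX2, a subunit gene of cytochrome oxidase, fell from 3852 ± 105 to 993 ± 96.9 CPM. Vdac1, the main channel of the mitochondrial outer membrane, fell from 124 ± 1.56 to 69.2 ± 5.86 CPM, a log2 change of -0.39 ± 0.06 (adjusted p = 6.82e-05). The list of outer membrane channels and import proteins was not called, with 20 of 38 lower and 7 higher (adjusted p = 0.0858, between 0.0184 and 0.509 over 17 alternatives). It was called with total counts (adjusted p = 0.0184), with the length trend taken out (adjusted p = 0.0242) and without SEN 1 (adjusted p = 0.0499). Bax, which opens that membrane in apoptosis, rose by 0.73 ± 0.08, while Bcl2, its inhibitor, had a log2 change of 0.81 ± 0.39 that did not pass the test (adjusted p = 0.07). Bcl2 was called higher in a fit of the 2 groups alone (adjusted p = 0.0293) and without BNPMT 3 (adjusted p = 0.0389), and over 22 alternatives its adjusted p ranged up to 0.397. The BCL2 family as a list was not called (8 of 16 higher, 5 lower, adjusted p = 0.214). Nuclear genes of oxidative phosphorylation were not called either (17 of 77 higher, 27 lower, 26 lower adjusted over the list alone, adjusted p = 0.271), nor were genes of mitophagy and mitochondrial dynamics, with a median of 0.18 that was -0.27 with total counts (18 of 36 higher, 9 lower, adjusted p = 0.128). With the length trend taken out the oxidative phosphorylation list had a median of -0.63, with 6 higher and 66 lower, and was called (adjusted p = 1.71e-05, the lowest of 17 alternatives, up to 0.864).

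Genes of DNA sensing, to which the title's extracellular DNA relates, were not called as a list, with 5 of 24 higher and 10 lower and a median of -0.17 (adjusted p = 0.673). With total counts 2 were higher and 19 lower, with a median of -0.62, and with the length trend taken out 3 and 17. Cgas, which encodes the cytosolic DNA sensor, fell from 7.57 ± 0.311 to 4.09 ± 0.406 CPM (log2 change -0.43 ± 0.11, adjusted p = 0.00311), and Sting1, the next step after it, had a log2 change of 0.57 ± 0.14 (adjusted p = 0.00216). The Sting1 call ended with total counts (log2 change 0.11, adjusted p = 0.462) and with both FPKM alternatives, and over 23 alternatives its adjusted p lay between 0.00024 and 0.5. Tlr9, the endosomal DNA receptor gene, had 1 count in NC and 6 in SEN, a ratio of 6.68 with a 95% counting interval of 0.811 to 307. Interferon-stimulated genes were not called (13 of 40 higher, 18 lower, adjusted p = 0.859), with a median of -0.24 and a mean of 0.24. Lists of cholesterol synthesis (9 of 25 higher, 11 lower, adjusted p = 0.694, median -0.08 and mean 0.17) and of TGF-beta targets (14 of 30 higher, 13 lower, adjusted p = 0.694) were not called. The TGF-beta list had a median of 0.09 under TMM and -0.36 with total counts, against a downward test, and the medians of S phase genes (-0.13, mean 0.00) and of genes lowered in senescence (-0.05, mean 0.20, upward test) also differed in sign from their means or tests.

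All 75 ribosomal protein genes rose in SEN, 74 of them with total counts as well, with a median of 1.03 (adjusted p = 1.84e-09, and adjusted p = 0.52 with an estimated correlation). The median was 0.58 with total counts and 0.47 with the length trend taken out. Rplp0 rose from 2215 ± 16.4 to 3602 ± 185 CPM, a log2 change of 1.15 under TMM, 0.70 with total counts and 0.76 with the length trend taken out. Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, rose in 14 of 17 cases and fell in 1, with a median of 3.07 (adjusted p = 0.0336, and adjusted p = 0.27 with an estimated correlation). Their summed level did not rise in SEN, at 351 CPM in NC, 287 CPM in SEN and 453 CPM in BNPMT. H2bc18 rose from 0.718 ± 0.151 to 23.4 ± 6.83 CPM, and Hist1h4b from 9.40 ± 0.427 to 39.6 ± 1.09 CPM. Histone copies share sequence, so single members are uncertain. That call was lost without BNPMT 1, which enters the shared spread (adjusted p = 0.0697), in a fit of the 2 groups alone (adjusted p = 0.0605), with a filter of 1 CPM in 3 libraries (adjusted p = 0.0902), with the length trend taken out (adjusted p = 0.0697) and without SEN 1 and BNPMT 1 together (adjusted p = 0.0768). Over 17 alternatives it lay between 0.00549 and 0.274.

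The largest rises in SEN were those of genes with almost no counts elsewhere. Ceacam19, an adhesion molecule gene, had 0 counts in NC and 27.4 ± 4.77 CPM in SEN, at least 1060-fold higher against a floor of 3 counts over the group. Stpg3 was at least 548-fold higher on the same floor. Trim72 rose from 0.0503 ± 0.0227 to 76.9 ± 5.36 CPM. Pou3f1 had 2 counts in NC and 2688 in SEN, a ratio per total count of 1500 with a counting interval of 414 to 12400, and Rab44 a ratio of 1260 with an interval of 348 to 10400. Over the 5394 genes with at most 6 counts in all NC and BNPMT libraries together, the sum was 33.5 ± 0.966 CPM in NC, 835 ± 39.6 CPM in SEN and 36.4 ± 0.489 CPM in BNPMT. The choice of these genes keeps the NC and BNPMT sums low, so only SEN was free to be higher. The largest falls were those of the connexin gene Gja5, from 11.6 ± 0.598 to 0.185 ± 0.0829 CPM, and of Irag1, Pars2, Ift70b and Cd200r1, by log2 changes of -4.36 ± 0.11 to -3.92 ± 0.15.

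Lists of markers of other cell types were followed too. Macrophage and leukocyte markers summed to 18.4 CPM in NC, 42.5 CPM in SEN and 24.4 CPM in BNPMT, endothelial markers to 41.0, 44.9 and 36.6 CPM, and skeletal muscle markers to 10.6, 12.8 and 7.23 CPM. Nerve and glia markers summed to 177, 221 and 213 CPM, osteoblast and hypertrophic markers to 1351, 1527 and 3923 CPM, of which Spp1 alone made 1228, 1415 and 3805 CPM, and erythroid markers, too few to test, to 0.143, 1.30 and 0.222 CPM. None of the 5 lists tested was called for SEN against NC: macrophage (6 of 11 higher, 4 lower, adjusted p = 0.0892), endothelial (5 of 9 higher, 2 lower, adjusted p = 0.42), osteoblast (10 of 15 higher, 2 lower, adjusted p = 0.0937), skeletal muscle (5 of 8 higher, 1 lower, adjusted p = 0.42) and nerve and glia (4 of 11 higher, 1 lower, adjusted p = 0.57, median 0.42 and -0.03 with total counts). With total counts the macrophage (adjusted p = 0.025) and osteoblast lists (adjusted p = 0.046) were called, and over 17 alternatives they ranged up to 0.348 and 0.272.

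Of 14956 genes tested with edgeR's quasi-likelihood test, 11382 (76.1%) changed between SEN and NC, 5628 higher and 5754 lower in SEN. With total counts the split was 3668 higher and 8512 lower, with limma on log2(FPKM + 1) 3651 and 8437, and with the length trend taken out 4693 and 7425. With total counts 405 genes were called in the opposite direction. At least a 2-fold change was found for 5178 genes, 2996 higher and 2182 lower under TMM, against 2142 higher and 4134 lower with total counts. CPM values of the groups did not overlap for 83.4% of tested genes, where chance gives 10%. Of 34 lists 16 were called with the preset correlation, and 10 of those calls were lost with an estimated correlation. That correlation gave the highest adjusted p of 17 alternatives for each of the 10, and the lowest lay between 5.15e-23 and 0.00797. Further medians of called lists that moved by over 1.5 times with total counts were those of p53 targets (0.35), G2 and mitosis (-1.06, 2 higher and 50 lower), genes raised in senescence (0.84, 15 and 6), mitochondrially encoded genes (-1.25, 0 and 13), NRF2 and antioxidant genes (0.32, 25 and 9), the unfolded protein response (0.07), lysosomal genes (0.49, 30 and 8) and glycolysis (0.36, 21 and 7). The medians with the length trend taken out were -1.53 for mitochondrially encoded genes, 0.20 for annulus markers, 0.42 for NRF2 genes and 0.26 for the unfolded protein response. Of the lists not called, total counts gave 8 higher and 21 lower for interferon-stimulated genes, 7 and 14 for nucleus pulposus markers, 6 and 17 for cholesterol synthesis, 8 and 17 for TGF-beta targets, 10 and 20 for mitophagy, 5 and 7 for the BCL2 family, 5 and 61 for oxidative phosphorylation, 2 and 34 for outer membrane genes, 4 and 8 for genes lowered in senescence and 16 and 13 for proteases.

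**Figure D2:**
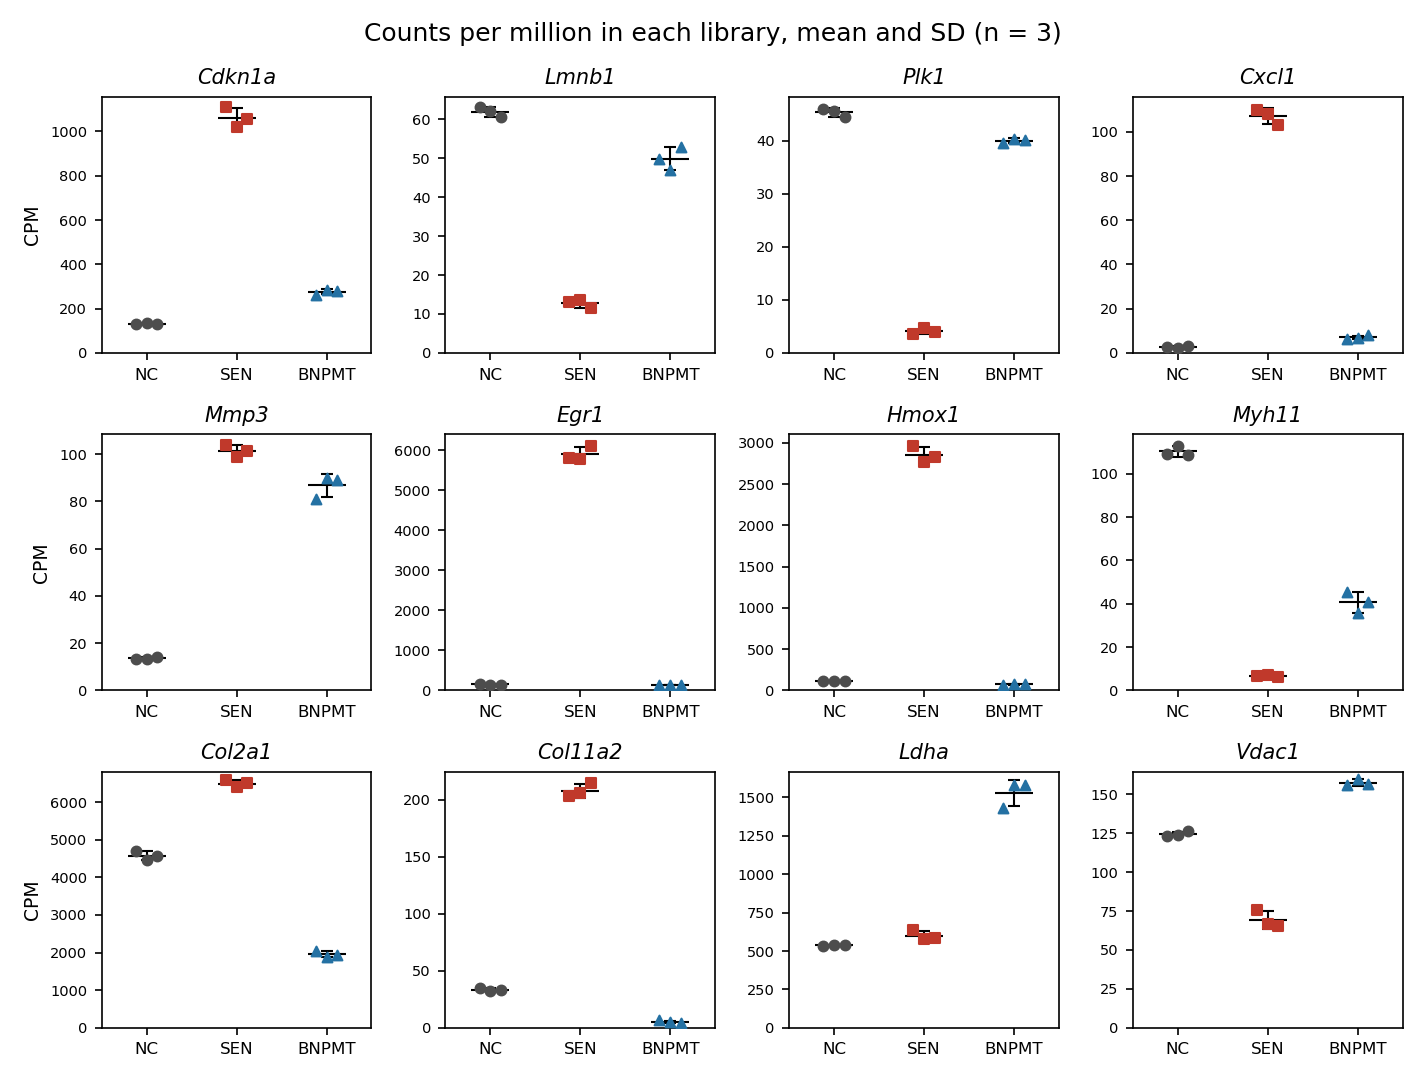
CPM of 12 named genes in each library, with points for libraries, horizontal bars for group means and error bars for the SD (n = 3). Cdkn1a lies at 1061 ± 45.5 CPM in SEN and 276 ± 11.2 in BNPMT, and Mmp3 at 101 ± 2.64 and 86.8 ± 4.93.

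The comparison of BNPMT with SEN asks what the intervention changed in doxorubicin-treated cells. Cdkn1a fell from 1061 ± 45.5 CPM in SEN to 276 ± 11.2 CPM in BNPMT (SD, n = 3), a log2 change of -2.45 ± 0.06 (SE, adjusted p = 1.96e-13). Lmnb1 rose from 12.8 ± 1.17 to 49.9 ± 2.94 CPM, and Plk1 from 4.08 ± 0.580 to 40.0 ± 0.415 CPM. Cxcl1 fell from 107 ± 3.53 to 6.99 ± 0.825 CPM, while Mmp3 fell from 101 ± 2.64 to 86.8 ± 4.93 CPM, a log2 change of -0.73 ± 0.06. Vdac1 rose from 69.2 ± 5.86 to 157 ± 2.18 CPM, a log2 change of 0.68 ± 0.06. Col2a1 fell from 6492 ± 84.3 to 1962 ± 87.1 CPM, and Acan from 681 ± 34.5 to 322 ± 31.4 CPM.

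Other fixed markers moved in both directions. Cdkn2a rose from 10.3 ± 0.846 to 23.1 ± 2.87 CPM (log2 change 0.66 ± 0.10, adjusted p = 3.98e-05). Glb1, Il6, Mmp13, Sox9 and Mki67 fell, with log2 changes of -0.85, -3.03, -1.95, -0.99 and -0.70. With total counts the values of Glb1, Sox9, Mki67 and Mmp3 were -0.34, -0.49, -0.20 and -0.22, and those of Cdkn2a, Adamts5, Sting1, Vdac1 and Bax 1.17, 0.92, 0.94, 1.18 and 0.69, each still called. In this comparison Adamts5 rose by 0.42 ± 0.15 (adjusted p = 0.023). The Adamts5 call ended in 5 of 23 alternatives, among them without BNPMT 1 (log2 change 0.20, adjusted p = 0.108), without SEN 1 (adjusted p = 0.0613) and without SEN 2 (adjusted p = 0.0571), and its adjusted p lay between 0.000102 and 0.232. The Mki67 call ended with the length trend taken out (log2 change -0.07, adjusted p = 0.146, the highest of 23 alternatives, down to 4.85e-25). Sting1 rose by 0.44 ± 0.13 and Bax by 0.18 ± 0.08 (adjusted p = 0.0402). The Bax call ended in 10 of 23 alternatives, among them a replicate block (adjusted p = 0.0542) and leaving out SEN 1, SEN 2, SEN 3, BNPMT 2 or BNPMT 3 (adjusted p = 0.0605, 0.0838, 0.0665, 0.161 and 0.0968), and its adjusted p lay between 9.27e-07 and 0.169. Without BNPMT 1 its log2 change was 0.29. Bcl2, at 0.771 ± 0.168 CPM in SEN and 0.270 ± 0.168 CPM in BNPMT, fell by 2.02. The direction of Cgas, which did not pass the test, depended on the scale: its log2 change was -0.19 ± 0.12 (adjusted p = 0.153) under TMM and 0.32 with total counts. It was called higher with total counts (adjusted p = 0.0221) and with both FPKM alternatives (adjusted p = 0.0162 and adjusted p = 0.0331), and over 23 alternatives its adjusted p ranged up to 0.425. Il1b had 0 counts in SEN and 1 in BNPMT. Tlr9 had 6 counts in SEN and 0 in BNPMT, at least 2.27-fold lower.

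Lists of p53 targets, inflammation and stress fell. Of 34 p53 targets 20 fell and 9 rose, against 15 and 16 with total counts, with a median log2 change of -0.54 (adjusted p = 2.55e-06), among them Plk2, from 561 ± 11.3 to 37.6 ± 0.810 CPM, and Plk3, from 139.9 ± 5.74 to 16.9 ± 1.24 CPM. Secretory genes fell in 39 of 55 cases and rose in 11 (40 and 11 adjusted over the list alone), with a median of -1.45 (adjusted p = 9.46e-10), and NF-kappaB targets fell in 22 of 30 and rose in 5, with a median of -1.29 (adjusted p = 2.55e-06). Ptgs2 fell from 1758 ± 268 to 42.9 ± 6.80 CPM, Plaur from 278 ± 9.51 to 17.7 ± 1.46 CPM, and Lif, a cytokine gene, from 59.1 ± 3.70 to 6.82 ± 0.210 CPM. Of 23 genes raised in senescence 16 fell and 6 rose, with a median of -0.66 (adjusted p = 0.00345, and adjusted p = 0.40 with an estimated correlation), while with total counts 12 fell and 9 rose, with a median of -0.16. Igfbp3, a secreted growth factor binding protein gene, fell from 238 ± 2.47 to 73.6 ± 2.77 CPM. The 13 genes lowered in senescence were not called (6 higher, 7 lower, adjusted p = 0.335, median -0.29 and 0.22 with total counts).

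Immediate early and heat shock genes fell in 31 of 32 cases, with a median of -3.37 (adjusted p = 1.05e-73), and with total counts 28 fell and 1 rose. The member that did not pass the test was the chaperonin gene Hspe1, singled out after its values were seen. Egr1 fell from 5900.1 ± 181 to 139.6 ± 3.27 CPM and Hspa1a from 935 ± 42.4 to 11.6 ± 0.864 CPM. Of 42 NRF2 and antioxidant genes 21 fell and 9 rose, with a median of -0.32 under TMM and 0.18 with total counts, where 19 rose and 13 fell (adjusted p = 0.0021, and adjusted p = 0.40 with an estimated correlation). Hmox1 fell from 2855 ± 97.2 to 75.3 ± 5.11 CPM, below the 110.3 ± 0.502 CPM of NC. Genes of the unfolded protein and amino acid stress responses fell in 27 of 40 cases and rose in 7, with a median of -0.61 (adjusted p = 1.32e-06, and adjusted p = 0.27 with an estimated correlation). With total counts 19 of them fell and 14 rose, with a median of -0.10. Dnajb9, a chaperone gene, fell from 434 ± 43.1 to 24.3 ± 0.119 CPM. Lysosomal genes fell in 33 of 43 cases and rose in 7, with a median of -0.51 under TMM and 0.00 with total counts (adjusted p = 0.0061, and adjusted p = 0.38 with an estimated correlation), and that call ended with total counts (16 higher, 18 lower, adjusted p = 0.137). Over 17 alternatives its adjusted p lay between 0.00131 and 0.38. Gla, a lysosomal galactosidase gene, fell from 101 ± 1.71 to 39.9 ± 2.88 CPM. Glycolysis and hypoxia genes were not called, with 15 of 34 higher, 15 lower and a median of -0.03 that was 0.47 with total counts (adjusted p = 0.221).

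Genes of G2 and mitosis rose in 43 of 57 cases and fell in 10, with a median of 0.76 (adjusted p = 4.51e-06). Ccnb1 rose from 9.5 ± 0.574 to 61.4 ± 1.81 CPM, and Cdc20, an activator of mitotic exit, from 10.8 ± 1.21 to 63.9 ± 1.53 CPM. S phase genes were not called (14 of 50 higher, 19 lower, adjusted p = 0.223), with a median of -0.03 under TMM and 0.48 with total counts. Genes of DNA repair were not called either (25 of 43 higher, 11 lower, adjusted p = 0.258).

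Of 5 mitochondrial lists 3 rose. Outer membrane channels and import genes rose in 27 of 38 cases and fell in 5, with a median of 0.58 (adjusted p = 0.00677, and adjusted p = 0.39 with an estimated correlation). Tomm40l, an import channel gene, rose from 5.42 ± 1.45 to 39.4 ± 1.66 CPM, and Mtx1, an outer membrane import and assembly gene, from 13.3 ± 0.664 to 49.6 ± 3.59 CPM. Nuclear genes of oxidative phosphorylation rose in 63 of 77 cases and fell in 3 (63 and 4 adjusted over the list alone), with a median of 0.65 (adjusted p = 2.61e-05, and adjusted p = 0.60 with an estimated correlation), among them Sdha, the flavoprotein gene of complex II, from 34.7 ± 1.66 to 131 ± 3.27 CPM. Mitochondrially encoded genes rose in 8 of 13 cases and fell in 2, with a median of 0.51 (adjusted p = 0.0133, and adjusted p = 0.38 with an estimated correlation), and COX2 rose from 993 ± 96.9 to 4368 ± 331 CPM. The BCL2 family (8 of 16 higher, 7 lower, adjusted p = 0.803) and mitophagy genes (13 of 36 higher, 13 lower, adjusted p = 0.863) were not called, with medians of 0.09 and 0.03 against downward tests. With total counts the BCL2 family had 10 higher and 5 lower, with a median of 0.59, and mitophagy genes 26 and 6, with a median of 0.53. Genes of DNA sensing (18 of 24 higher, 4 lower, adjusted p = 0.195) and interferon-stimulated genes (19 of 40 higher, 7 lower, 6 lower adjusted over the list alone, adjusted p = 0.343) were not called.

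Matrix genes of the cartilage type fell in 33 of 37 cases and rose in 1, with a median of -2.10 (adjusted p = 5.93e-18). Col11a2 fell from 208 ± 5.91 to 5.54 ± 0.960 CPM and Fmod, the fibromodulin gene, from 626 ± 10.2 to 99.6 ± 2.44 CPM. Annulus and fibroblast markers fell in 22 of 29 cases and rose in 4, with a median of -1.11 (adjusted p = 1.95e-07), among them Eln, from 732 ± 17.1 to 49.7 ± 1.31 CPM, and Col14a1, from 3586 ± 178 to 761 ± 75.6 CPM. Smooth muscle markers rose in 16 of 20 cases and fell in 3, with a median of 0.69 (adjusted p = 0.0128, and adjusted p = 0.091 with an estimated correlation), and Acta2 rose from 389 ± 21.2 to 1145 ± 53.5 CPM. Matrix-degrading proteases (13 of 33 higher, 19 lower, 20 lower adjusted over the list alone, adjusted p = 0.226) and nucleus pulposus markers (11 of 24 higher, 10 lower, adjusted p = 0.775, median 0.23 against a downward test) were not called. TGF-beta targets were not called (12 of 30 higher, 14 lower, adjusted p = 0.412, median -0.05 and 0.46 with total counts).

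Cholesterol synthesis genes rose in 19 of 25 cases and fell in 5, with a median of 0.80 (adjusted p = 0.00529, and adjusted p = 0.059 with an estimated correlation). Fdft1, which encodes squalene synthase, rose from 32.4 ± 1.63 to 208 ± 5.55 CPM, and Dhcr7, an enzyme gene of the last steps, from 15.4 ± 0.438 to 98.5 ± 2.66 CPM. Ribosomal protein genes fell in 74 of 75 cases under TMM, with a median of -0.60 (adjusted p = 0.00276, and adjusted p = 0.68 with an estimated correlation), while with total counts 20 fell and 2 rose, with a median of -0.10. Histone genes were not called, with 13 of 17 lower and 2 higher (adjusted p = 0.164). The macrophage (5 of 11 higher, 6 lower, adjusted p = 0.164), endothelial (1 of 9 higher, 4 lower, adjusted p = 0.223), osteoblast (2 of 15 higher, 10 lower, adjusted p = 0.164), skeletal muscle (1 of 8 higher, 5 lower, adjusted p = 0.277) and nerve lists (1 of 11 higher, 7 lower, adjusted p = 0.423) were not called. With total counts the histone and macrophage lists were called (adjusted p = 0.0393 for each), and over 17 alternatives they ranged up to 0.412 and 0.497.

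The largest falls were those of Ceacam19, Pou3f1, Cimap2, Trim72 and Stpg3. Trim72 fell to 0.092 ± 0.0955 CPM, a log2 change of -10.15 ± 0.22. Cimap2 had 3048 counts in SEN and 3 in BNPMT, a ratio per total count of 1150 with a counting interval of 393 to 5580. The largest rises were those of Gja5, to 16.1 ± 0.848 CPM, the lactate exporter gene Slc16a3, from 0.992 ± 0.204 to 54.8 ± 1.65 CPM, the epithelial keratin gene Krt7, from 0.888 ± 0.495 to 37.4 ± 2.87 CPM, Ift70b, and the joint growth factor gene Gdf5, from 0.478 ± 0.243 to 16.1 ± 1.5 CPM.

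Between BNPMT and SEN 12061 genes (80.6%) changed, 6092 higher and 5969 lower in BNPMT. With total counts the split was 8573 higher and 3858 lower, and with limma on log2(FPKM + 1) 8486 and 3782. With total counts 554 genes were called in the opposite direction. At least a 2-fold change was found for 5899 genes, 2605 higher and 3294 lower under TMM, against 4883 higher and 2294 lower with total counts. CPM values did not overlap for 82.5% of genes, where chance gives 10%. Of 34 lists 17 were called, and 10 of those calls were lost with an estimated correlation, which gave each of the 10 its highest adjusted p of 17 alternatives, with the lowest between 4.11e-12 and 0.00497. Further medians of called lists that moved by over 1.5 times with total counts were those of p53 targets (-0.04), G2 and mitosis (1.26, 49 higher and 5 lower), secretory genes (-0.95, 13 and 33), NF-kappaB targets (-0.79, 8 and 18), outer membrane genes (1.08, 34 and 1), mitochondrially encoded genes (1.02, 11 and 1), oxidative phosphorylation (1.16, 75 and 1), annulus markers (-0.61, 7 and 20), smooth muscle markers (1.19, 17 and 1) and cholesterol synthesis (1.30, 20 and 4). The medians of p53 targets and NRF2 genes were -0.30 and -0.18 with the length trend taken out. Of the lists not called, total counts gave 34 higher and 13 lower for S phase genes, 31 and 6 for DNA repair, 20 and 2 for DNA sensing, 25 and 4 for interferon-stimulated genes, 19 and 13 for glycolysis, 18 and 10 for TGF-beta targets, 13 and 9 for nucleus pulposus markers, 14 and 16 for proteases and 7 and 5 for genes lowered in senescence.

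Most genes that changed in SEN against NC changed the other way in BNPMT against SEN. The groups are separate libraries without a time course, and the timing of BNPMT is not given. A change that was undone therefore cannot be told apart from one that never arose. Handling or batch of SEN alone would give the same pattern and cannot be told apart either. Of the 11382 genes changed in SEN 9704 (85.3%) changed in the opposite direction in BNPMT against SEN. Of those 4851 were higher in SEN than in both other groups, and 4853 were lower. A further 355 genes changed in the same direction in both comparisons, and 1323 did not pass the test in BNPMT against SEN. Ceacam19, Pou3f1, Trim72, Rab44, Egr4, Btk and Pcdh17 were among the most strongly reversed. Btk, a kinase gene known from B cells, went from 0.0418 ± 0.026 CPM in NC to 35.9 ± 3.24 in SEN and 0.0588 ± 0.036 in BNPMT. The median share undone, as defined above, was 1 (quartiles 0.68 and 1.33), where 1 is the NC level. It ranged from 0.992 to 1.012 over the BNPMT libraries. Of the reversed genes 4931 were not called between BNPMT and NC, 1703 lay short of the NC level and 3070 lay past it.

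Both comparisons use the same SEN libraries, which alone makes their changes run opposite. In 20 simulations of unchanged groups 0 genes were reversed with edgeR, a count that says nothing of the observed one, since such groups give almost no calls. Independent lists of the observed sizes would share 4590 genes with opposite signs. The observed correlation of the log2 changes across genes, which are not independent replicates, was -0.94 against a simulated -0.55. The covariance was -3.27 against -0.0205, a difference of -3.25. With the SEN libraries split between the comparisons, the median share undone was 0.981 to 0.99. Each split left 1 SEN library on one side, and the count of reversed genes was not recomputed with it. Part of the observed count and of the correlation may come from the shared libraries.

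The comparison of BNPMT with NC asks how cells given doxorubicin and BNPMT differed from control cells. No group had BNPMT without doxorubicin, so remaining effects of the drug cannot be told apart from effects of BNPMT itself. Not every difference was left over from SEN: Col2a1 was higher in SEN than in NC and lower in BNPMT. Cdkn1a stayed higher than in NC, at 276 ± 11.2 against 133 ± 1.91 CPM (SD, n = 3), a log2 change of 1.01 ± 0.06 (SE, adjusted p = 2.98e-08). Mmp3 was higher at 86.8 ± 4.93 against 13.6 ± 0.514 CPM, and Spp1, the osteopontin gene, at 3805 ± 155 against 1228 ± 17.6 CPM. Matrix genes were lower, with Col2a1 at 1962 ± 87.1 against 4571 ± 119 CPM, Acan at 322 ± 31.4 against 587 ± 10.4 CPM and Col1a1, the main fibrillar collagen gene, at 13039 ± 1124 against 30449.5 ± 618 CPM. The glycolytic gene Ldha was higher at 1529 ± 85.3 against 538 ± 4.54 CPM. Vdac1 was higher at 157 ± 2.18 against 124 ± 1.56 CPM, a log2 change of 0.29 ± 0.06 (adjusted p = 0.00175). That call ended with the length trend taken out (log2 change 0.095, adjusted p = 0.106, the highest of 23 alternatives, down to 4.96e-06).

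This comparison carried a trend with transcript length. The median log2 change fell from 0.48 in the shortest 10% of tested genes to -0.39 in the longest 10%, and the Spearman correlation with length was -0.48 across genes. It was -0.03 for SEN against NC and -0.16 for BNPMT against SEN. BNPMT 1 differed from the other BNPMT libraries along the same axis (0.51). With the trend taken out 6884 genes were called, 5447 shared with the same sign. Among called lists, besides those below, medians moved by over 1.5 times for genes raised in senescence (0.22), secretory genes (0.17) and NF-kappaB targets (0.21). So did those of outer membrane genes (0.14), annulus markers (-0.33), NRF2 genes (0.16) and TGF-beta targets (-0.16). All stayed called.

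**Figure D3:**
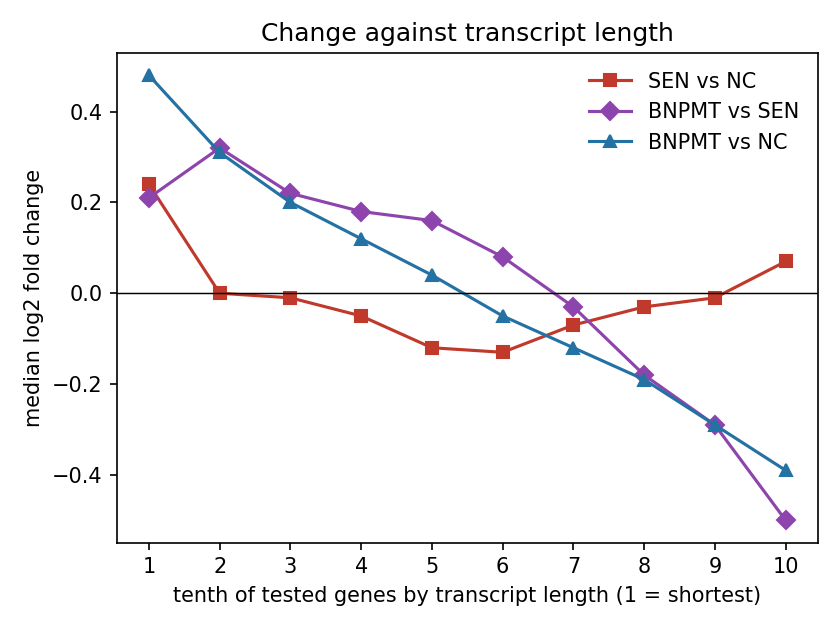
Median log2 fold change (y axis, TMM scaling) of the tested genes in each of 10 bins of transcript length (x axis, 1 is the shortest), for the 3 comparisons. The BNPMT against NC line falls from 0.48 to -0.39; with total counts the medians over all genes are -0.46 for SEN against NC and 0.52 for BNPMT against SEN, so the side of 0 depends on the scale there.

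Other fixed markers also differed from NC. Cdkn2a rose to 23.1 ± 2.87 from 10.9 ± 0.187 CPM (log2 change 1.03 ± 0.10), Cxcl1 by 1.34 ± 0.12, Mmp13 by 0.57 ± 0.09 and Bax by 0.91 ± 0.08. Sting1 rose from 6.22 ± 0.593 to 12.9 ± 2.07 CPM, and Cgas fell from 7.57 ± 0.311 to 5.09 ± 0.115 CPM. Lmnb1, Mki67, Sox9 and Adamts5 fell, with log2 changes of -0.36, -0.61, -0.57 and -1.17. Bcl2, below 1 CPM in both groups, fell by 1.2 (adjusted p = 0.0336). The Bcl2 call ended without NC 1, NC 3, BNPMT 2 or BNPMT 3 (adjusted p = 0.116, 0.069, 0.0657 and 0.134), and over 22 alternatives its adjusted p lay between 0.00837 and 0.134. Glb1 at 0.03 ± 0.06 (adjusted p = 0.738) and Il6 at 0.56 ± 0.49 (adjusted p = 0.356) did not pass the test. Il1b and Tlr9 had at most 1 count in either group. With the length trend taken out Cdkn2a, Mki67, Cgas and Bax were still called, at log2 changes of 0.58, -0.27, -0.41 and 0.50.

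Lists of damage and inflammation stayed above NC, with smaller medians than in the comparison of SEN with NC, a difference that was not tested. Of 34 p53 targets 20 rose and 5 fell (20 and 6 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.000146), with Mdm2 at 169.9 ± 3.50 against 70.8 ± 2.85 CPM and the cyclin gene Ccng1 at 535 ± 24.9 against 252 ± 12.3 CPM. Of 23 genes raised in senescence 15 rose and 4 fell, with a median of 0.47 (adjusted p = 2.82e-09, and adjusted p = 0.075 with an estimated correlation). Secretory genes rose in 26 of 55 cases and fell in 11 (26 and 12 adjusted over the list alone), with a median of 0.26 (adjusted p = 3.66e-05), and NF-kappaB targets rose in 16 of 30 and fell in 5, with a median of 0.38 (adjusted p = 0.00522). Without SEN 1 and BNPMT 1 the call of NF-kappaB targets ended (adjusted p = 0.0534, the highest of 17 alternatives, down to 0.0029). Lcn2, which encodes an iron-binding acute phase protein, rose from 1.55 ± 0.152 to 7.47 ± 0.862 CPM, and the prostaglandin synthase gene Ptges from 4.49 ± 0.157 to 14.7 ± 0.924 CPM. The 13 genes lowered in senescence (2 higher and 7 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.0686) and matrix-degrading proteases (13 of 33 higher and 9 lower, 14 and 9 adjusted over the list alone, adjusted p = 0.1) were not called. With the length trend taken out both were called (adjusted p = 0.0167 and adjusted p = 0.0245), as proteases were without BNPMT 3 (adjusted p = 0.0437). Over 17 alternatives they ranged up to 0.213 and 0.534.

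Interferon-stimulated genes rose in 17 of 40 cases and fell in 3, with a median of 0.24 (adjusted p = 0.0217, and adjusted p = 0.07 with an estimated correlation), among them the regulator gene Irf7, from 2.92 ± 0.418 to 5.80 ± 0.327 CPM. Without BNPMT 1 that call ended (adjusted p = 0.0592), as it did with the length trend taken out (adjusted p = 0.0649), and over 17 alternatives it lay between 0.00674 and 0.0701. Genes of DNA sensing rose in 12 of 24 cases and fell in 5, with a median of 0.29 (adjusted p = 0.0137, and adjusted p = 0.12 with an estimated correlation). Dnase2, the lysosomal DNA-degrading enzyme gene, rose from 28.8 ± 0.778 to 58.8 ± 4.17 CPM, and Tbk1, a kinase gene downstream of STING, by 0.39 ± 0.05. Immediate early and heat shock genes were not called, with 8 of 32 higher and 11 lower and a median of 0.00 (adjusted p = 0.68), where the mean of -0.05 and the test pointed down, and with total counts 9 were higher and 8 lower. With the length trend taken out the list was called as lower (adjusted p = 0.0151, the lowest of 17 alternatives, up to 0.98).

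Of 5 mitochondrial lists 4 were higher than in NC, all of nuclear genes. Nuclear genes of oxidative phosphorylation rose in 76 of 77 cases and fell in 0, with a median of 0.56 (adjusted p = 7.94e-17, and adjusted p = 0.31 with an estimated correlation). Their median transcript length was 823 nt, and with the length trend taken out the median change was 0.13, with 42 higher and 1 lower (adjusted p = 0.00042). Cox7a2, a cytochrome oxidase subunit gene, rose from 65.7 ± 3.76 to 121 ± 13.3 CPM. Outer membrane channels and import genes rose in 21 of 38 cases and fell in 6 (22 and 6 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00709, and adjusted p = 0.30 with an estimated correlation). Tspo, an outer membrane protein gene, rose from 89.8 ± 4.15 to 148 ± 15 CPM, and Samm50, of the outer membrane assembly machinery, from 68.5 ± 2.69 to 101 ± 5.59 CPM. The log2 changes of Cox7a2, Tspo and Samm50, 0.83, 0.67 and 0.51, were 0.31, 0.28 and 0.28 with the length trend taken out. The BCL2 family rose in 10 of 16 cases and fell in 4, with a median of 0.27 (adjusted p = 0.00631, and adjusted p = 0.056 with an estimated correlation), and mitophagy genes rose in 21 of 36 and fell in 3, with a median of 0.28 (adjusted p = 0.000182, and adjusted p = 0.075 with an estimated correlation). Bnip3, a mitophagy receptor gene induced at low oxygen, rose from 37.8 ± 0.745 to 91.7 ± 3.77 CPM. Mitochondrially encoded genes were not called (2 of 13 higher and 7 lower, 4 and 3 with total counts, adjusted p = 0.553), except as lower with the length trend taken out (adjusted p = 9.56e-05, the lowest of 17 alternatives, up to 0.736).

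Glycolysis and hypoxia genes rose in 27 of 34 cases and fell in 2, with a median of 0.65 (adjusted p = 2.16e-25). Besides Ldha, Tpi1, which encodes a glycolytic isomerase, rose from 245 ± 3.02 to 701 ± 41.6 CPM, and Slc16a3 from 4.52 ± 0.340 to 54.8 ± 1.65 CPM. Cholesterol synthesis genes rose in 22 of 25 cases and fell in 1, with a median of 0.74 (adjusted p = 2.09e-21), with Insig1, a sterol sensor gene, at 483 ± 8.04 against 223 ± 3.81 CPM and Acat2, an acetyl-CoA acetyltransferase gene, at 390.2 ± 24.8 against 169.5 ± 5.87 CPM. NRF2 and antioxidant genes rose in 23 of 42 cases and fell in 8 (23 and 10 adjusted over the list alone), with a median of 0.39 (adjusted p = 3.66e-05, and adjusted p = 0.24 with an estimated correlation). The metallothionein gene Mt1, which encodes a metal-binding protein, rose from 7.49 ± 1.0 to 35.9 ± 4.60 CPM. Lysosomal genes rose in 25 of 43 cases and fell in 2 (27 and 2 adjusted over the list alone), with a median of 0.28 (adjusted p = 6.51e-08, and adjusted p = 0.056 with an estimated correlation), among them Ctsl, from 772 ± 10.3 to 1374 ± 86.9 CPM, a log2 change of 0.78 and of 0.50 with the length trend taken out. Ribosomal protein genes, with a median length of 711 nt, rose in 73 of 75 cases with a median of 0.45 (adjusted p = 2.61e-11, and adjusted p = 0.42 with an estimated correlation). With the length trend taken out their median was -0.01 and the call ended (adjusted p = 0.764, the highest of 17 alternatives, down to 1.79e-31).

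Matrix and contractile lists were lower than in NC. Cartilage-type genes fell in 28 of 37 cases and rose in 0 (28 and 1 adjusted over the list alone), with a median of -0.84 (adjusted p = 2.25e-25), and with total counts 28 fell and 2 rose. Their median transcript length was 4037 nt, and with the length trend taken out the median change was -0.63. Col11a2 fell from 33.6 ± 0.973 to 5.54 ± 0.960 CPM and Cilp, a cartilage matrix gene, from 223 ± 2.37 to 65.0 ± 4.65 CPM. Annulus and fibroblast markers fell in 21 of 29 cases and rose in 4 (22 and 4 adjusted over the list alone), with a median of -0.52 (adjusted p = 3.54e-16), and Eln fell from 235 ± 3.62 to 49.7 ± 1.31 CPM. Smooth muscle markers fell in 14 of 20 cases and rose in 3, with a median of -0.49 (adjusted p = 2.05e-08), with Myh11 at 40.7 ± 4.95 against 110.3 ± 2.38 CPM. TGF-beta targets fell in 16 of 30 cases and rose in 7, with a median of -0.32 (adjusted p = 0.000193), among them Postn, from 1051 ± 30.9 to 662 ± 10.9 CPM. Nucleus pulposus markers were not called (6 of 24 higher and 9 lower, 6 and 11 adjusted over the list alone, adjusted p = 0.781).

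S phase genes fell in 33 of 50 cases and rose in 3, with a median of -0.39 (adjusted p = 3.66e-05), while genes of G2 and mitosis were not called, with 16 of 57 higher and 19 lower (18 and 20 adjusted over the list alone, 22 and 16 with total counts, adjusted p = 0.68). Uhrf1, which maintains DNA methylation at replication, fell from 53.4 ± 1.82 to 29.5 ± 4.09 CPM, and Mcm5, a subunit gene of the replicative helicase, from 59.1 ± 1.51 to 41.4 ± 1.76 CPM. Genes of the unfolded protein and amino acid stress responses fell in 30 of 40 cases and rose in 2, with a median of -0.36 (adjusted p = 6.12e-11, and adjusted p = 0.075 with an estimated correlation). The asparagine synthetase gene Asns fell from 244 ± 6.39 to 155 ± 3.27 CPM. Genes of DNA repair (6 of 43 higher, 20 lower, adjusted p = 0.1) and histone genes (7 of 17 higher, 4 adjusted over the list alone, 0 lower, adjusted p = 0.0958) were not called. Histone genes were called with a filter of 1 CPM in 3 libraries (adjusted p = 0.0227) and without NC 1 (adjusted p = 0.0439), and over 17 alternatives they ranged up to 0.515.

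Largest among the rises against NC were Slc16a3, Aldh3a1, a detoxifying dehydrogenase gene (from 1.12 ± 0.259 to 10.6 ± 0.541 CPM), Mmp3, Klhl40 and Mt1. Among the falls H19, an imprinted non-coding RNA, went from 249 ± 3.85 to 39.0 ± 2.09 CPM, and Col11a2, Eln and Aoc3 were also among the 5 largest. The endothelial (2 of 9 higher and 3 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.274), macrophage (1 of 11 higher and 1 lower, 1 and 0 adjusted over the list alone, adjusted p = 0.68), osteoblast (3 of 15 higher and 6 lower, 4 and 7 adjusted over the list alone, adjusted p = 0.887), skeletal muscle (0 of 8 higher, 1 lower, adjusted p = 0.563) and nerve lists (2 of 11 higher, 2 lower, adjusted p = 0.69) were not called. The osteoblast list had a median of -0.37 against an upward test, and the skeletal muscle list a median of -0.03 and a mean of 0.01.

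Between BNPMT and NC 7903 genes (52.8%) changed, 3933 higher and 3970 lower in BNPMT, and with total counts 4518 were higher and 3364 lower. At least a 2-fold change was found for 938 genes, 399 higher and 539 lower, against 467 and 483 with total counts. CPM values did not overlap for 61.7% of genes, where chance gives 10%. Of 34 lists 21 were called, and 11 of those calls were lost with an estimated correlation. Except for ribosomal proteins that gave the highest adjusted p of 17 alternatives for each of the 11, with the lowest between 1.79e-31 and 0.00816.

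**Figure D4:**
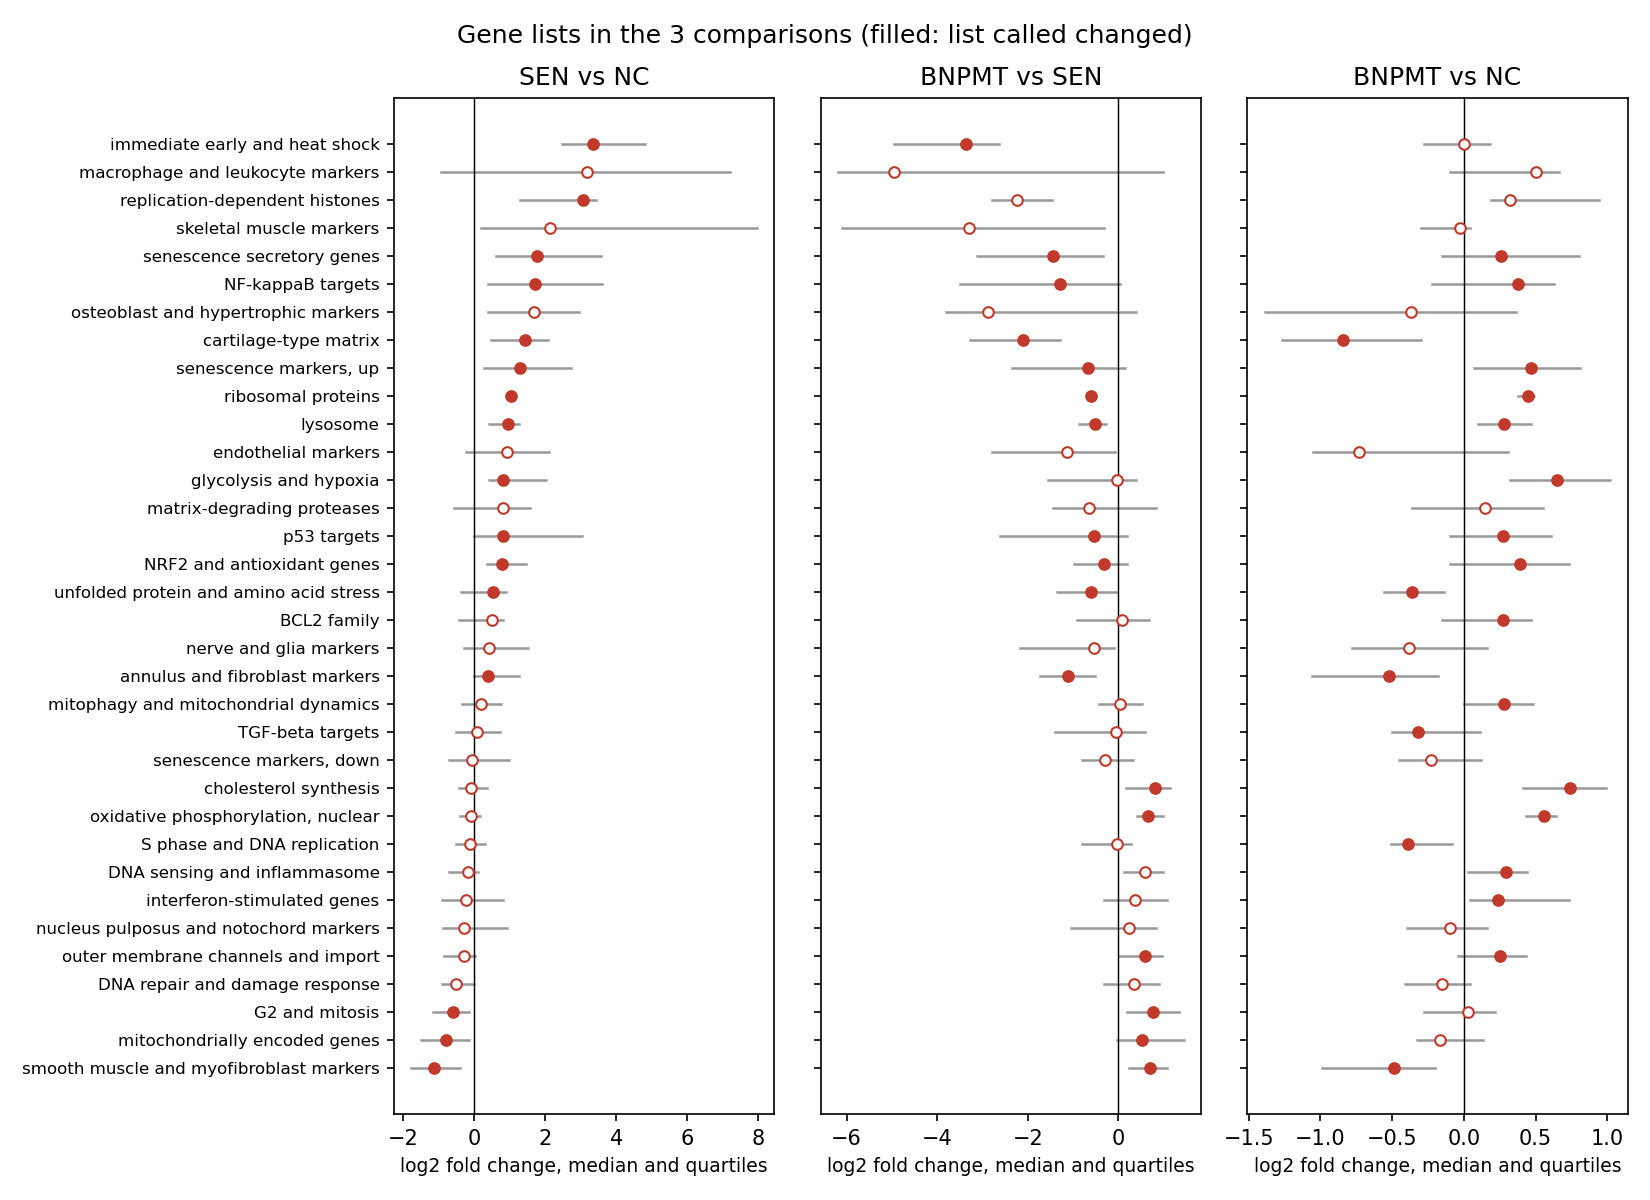
Median (points) and quartiles (lines) of the members' log2 fold changes under TMM scaling for 34 gene lists in the 3 comparisons, with filled points for lists called changed by camera at an adjusted p below 0.05; the x axes differ in range. Immediate early and heat shock genes have medians of 3.35, -3.37 and 0.00; with total counts the sign of the median flips for annulus markers (SEN against NC) and for NRF2 genes (BNPMT against SEN) among the called lists.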

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

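The 3 alternatives chosen after seeing the data are named above. The number of genes called stayed within 1.5 times under every alternative but the 2-fold minimum, which left 5178 genes for SEN against NC, 5899 for BNPMT against SEN, 938 for BNPMT against NC and 4264 reversed, as a stricter criterion must give fewer. Leaving out 1 library gave 11070 to 11928, 11758 to 12299 and 6538 to 8525 called genes, 9421 to 9968 reversed genes, a median share undone of 0.998 to 1.009, and 15 to 18, 17 and 20 to 22 lists. Without SEN 1 and BNPMT 1 the counts were 11749, 12155, 9045 and 9811, and with the length trend out 12118, 12401, 6884 and 10782. The median share undone moved by more than 1 SD over the BNPMT libraries with limma on log2(FPKM + 1), 1.017, and on log2(FPKM + 0.1), 1.021, with total counts, 1.023, with the length trend out, 1.014, without SEN 1 and BNPMT 1, 1.013, and with SEN 2 or SEN 3 held apart, 0.981 and 0.985. An estimated correlation left 6, 7 and 10 of the called lists, and fry, which does not compare a list with other genes, called 31, 34 and 27. In SEN against NC these included proteases, DNA repair and outer membrane genes (fry, adjusted p = 1.85e-06, 3.9e-06 and 0.000274). The cause was not tested.

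With a replicate block 11143, 11842 and 7348 genes were called, 9497 reversed, with a share undone of 1 and 16, 17 and 22 lists. The list gained was DNA repair in BNPMT against NC (adjusted p = 0.0441, with camera, and up to 0.312 over 17 alternatives). The numbers do not pair the libraries: deviations of the 9 same-numbered pairs correlated at -0.24 to 0.06, none above 0.1, and 0 of 9 libraries lay closest to their own number.

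Of 6701 values of the named genes reported here under alternatives 6574 kept direction and side of the threshold, 93 lost the call (69 with the 2-fold minimum), 3 gained it and 31 turned. For SEN against NC, under log2(FPKM + 1), log2(FPKM + 0.1), total counts and length trend out, Cdkn2a had log2 changes of -0.082, -0.087, -0.084 and -0.183, Mki67 -0.332, -0.361, -0.361 and -0.199, and Sox9 -0.024, -0.027 and -0.024 under those but the last. For BNPMT against SEN, Cgas had 0.135, 0.28, 0.316 and 0.207 under all 4. The other 16 turned values were in BNPMT against NC, in genes not called there. Leaving out 1 library, Glb1 ranged from -0.029 to 0.072 (-0.001 without NC 2, and -0.011 with the length trend out). Pou3f1 ranged from -2.508 to 0.473, with 0.334 without NC 1, 0.22 without NC 3, 0.473 without BNPMT 1, 0.355 without BNPMT 2 and 0.471 without SEN 1 and BNPMT 1. Egr4 ranged from -0.15 to 1.084, with -0.15 without NC 1, -0.145 without BNPMT 2 and -0.028 without BNPMT 3. Btk ranged from -0.164 to 0.989, with -0.164 without BNPMT 1 and -0.168 without SEN 1 and BNPMT 1. Ceacam19, Trim72 and Pcdh17 ranged up to 2.152, 1.37 and 1.064, and without BNPMT 3 had 0, -0.413 and -0.035. The cause was not tested. Depth limits genes near the floor, such as Tlr9 and Il1b.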

Other observations

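The KEGG tests, the tests of the immediate early genes and of genomic DNA, the interval beside the length test and the unadjusted counts of other splits were chosen after the results were seen. Genes of aminoacyl-tRNA biosynthesis, which charge tRNAs for translation, fell in SEN in 40 of 45 cases and rose in 5, with a median log2 change of -0.91 (camera, adjusted p = 4.78e-07, and adjusted p = 0.099 with an estimated correlation). In BNPMT against SEN 38 rose and 5 fell, with a median of 0.92 (adjusted p = 4.92e-05, and adjusted p = 0.19 with an estimated correlation). Genes of complement and coagulation rose in SEN in 35 of 44 cases and fell in 6, with a median of 1.02 (adjusted p = 5.24e-05, and adjusted p = 0.099 with an estimated correlation). Those of antigen processing rose in 41 of 57 cases and fell in 5, with a median of 0.98 (adjusted p = 6.58e-07, and adjusted p = 0.23 with an estimated correlation). The IL-17 signalling pathway had 41 of 67 genes higher and 18 lower (adjusted p = 4.32e-08, and adjusted p = 0.052 with an estimated correlation).

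Between BNPMT and NC, genes of fatty acid degradation rose in 25 of 37 cases and fell in 2, with a median of 0.44 (camera, adjusted p = 8.08e-07, and adjusted p = 0.29 with an estimated correlation). Peroxisome genes rose in 45 of 77 cases and fell in 4 (adjusted p = 2.84e-06, and adjusted p = 0.29 with an estimated correlation), and genes of xenobiotic metabolism by cytochrome P450 in 24 of 39 cases, with 0 lower (adjusted p = 2.47e-07, and adjusted p = 0.29 with an estimated correlation). Proteasome genes, with a median length of 1390 nt, rose in 40 of 45 cases and fell in 3 (adjusted p = 5.2e-07, and adjusted p = 0.46 with an estimated correlation). Genes of the interaction of matrix and receptors, with a median length of 5682 nt, fell in 44 of 72 cases and rose in 12 (adjusted p = 2.11e-11, and adjusted p = 0.39 with an estimated correlation). Of 308 pathways 53, 68 and 85 were called in the 3 comparisons with the preset correlation, and the smallest adjusted p with an estimated correlation was 0.052, 0.14 and 0.28.

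The immediate early and heat shock genes were high in SEN alone. Scaling by library composition is argued against by their median log2 change of 2.9 with total counts. Doxorubicin exposure alone cannot be told apart from senescence: the list's median was 0 in BNPMT against NC, yet BNPMT, of unknown timing, may undo an effect of the drug. Handling of the SEN cultures at harvest cannot be told apart either: the list's mean log2 CPM had an SD of 0.031 over the SEN libraries, and the labels name no SEN library harvested another way. An effect of senescence that BNPMT prevents stays open beside both.

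Short transcripts were higher and long transcripts lower in BNPMT than in NC, a pattern that RNA quality or library preparation could give. With the length trend taken out of every library, the median log2 change of ribosomal protein genes was -0.01 (bootstrap interval -0.05 to 0.01), so the trend may account for their rise. The median of cartilage-type matrix genes was -0.63 (-1.06 to -0.40), which argues against the trend as the whole source of that change. The median of nuclear oxidative phosphorylation genes was 0.13 (0.11 to 0.17), which does not decide. These intervals resample list members as if independent and do not cover the spread between libraries. The oxidative phosphorylation genes had an estimated correlation of 0.871. Across genes a Spearman correlation with length of -0.05 was left after the removal. Most of the oxidative phosphorylation rise, 0.56 before, went with length. Whether the trend itself came from the cells or from the libraries stays open.

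Genes with at most 6 counts over the NC and BNPMT libraries held 835 ± 39.6 CPM in SEN, and 408 of 5394 had at least 30 counts there. Genomic DNA that gives counts by length is argued against: the 540 genes with most counts in 1 SEN library held 80.5% to 81.2% of the counts in the other 2 and 11.8% to 12.4% of the length, a ratio of 6.48 to 6.86. Macrophages are argued against too, since the mean rise of 5 abundant macrophage transcripts minus that of the macrophage surface genes Itgam and Mrc1 was -4.33 CPM, with Lyz2 at 1.55 CPM in SEN, Itgam at 3.97 and Mrc1 at 5.15. Transcription running on from neighbouring genes may account for part: the median log2 change of the larger-changed neighbour was 0.17 higher for raised silent genes (0.23 against 0.07, one-sided permutation p = 0.006), as for Rab44 beside Cdkn1a (3.45), yet of the 287 raised genes beside a gene of at least 1 CPM in NC 72.8% had no such neighbour raised 2-fold, with neighbours below that level not counted. The rest stays open, a loss of silencing in senescent cells included, as untested.

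With 3 libraries against 3 there are 10 splits, so the share of splits with as many calls cannot fall under 0.05. With edgeR the real split gave 11382, 12061 and 7903 genes in the 3 comparisons, and the highest other split gave 0 in each. At an unadjusted p under 0.05 the highest other splits gave 98, 679 and 772 genes.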
